A study of Mus musculus with 12 samples.

How the data were processed

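Single cells from mouse skin and excisional wounds were profiled by droplet-based RNA sequencing on the 10x Genomics platform (Single Cell 3' v3). Each captured transcript carries a unique molecular identifier (UMI) and is read near its 3' end. There were 12 libraries from C57BL/6 mice. Per the labels, the GDB arm came from db/db mice (genotype B6.BKS(D)-Leprdb/J), the PDB arm from wildtype mice on a high-fat diet and the NDB arm from wildtype mice. The labels call the genetic model a leptin-receptor knockout in one place and db/db in another, and the genotype entry was used here. Every arm had unwounded skin (POD 0) and wounds at POD 2, 7 and 30, where POD was read as the day after wounding. Each arm and day had 1 library. The number of animals behind a library is not stated, so a library could hold 1 animal or several. No paired analysis was possible because each arm and day has 1 library and nothing in the labels links animals across days.

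Per the submitters' processing notes, reads were processed with Cell Ranger against the mouse build mm10 (GRCm38) and analysed further with Seurat 3.1.1. The deposited matrices hold counts, whole numbers of UMIs per gene and cell barcode, without normalization. Per the file headers, Cell Ranger 6.0.0 wrote the matrices of 5 libraries (GDB day 2 and day 7, and NDB day 0, day 2 and day 7) and Cell Ranger 7.0.0 those of the other 7. The later release counts intronic reads by default and the earlier one does not, and the setting used is not stated. The 7 later matrices also list 10 antibody hashtag features, which hold 0 counts. The PDB arm lies wholly in the later version, so a difference of PDB can be partly one of version, from NDB at days 0, 2 and 7 and from GDB at days 2 and 7. Within 1 version, GDB and NDB can be set side by side at days 2 and 7, GDB and PDB at days 0 and 30, and all 3 arms at day 30.

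The matrices were read with Python 3.11.15 (scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). Barcodes with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were taken as cells, 147,677 of 181,354. Scrublet, run within each library, marked doublets. Its own threshold was used in 4 libraries, and in the other 8, where it marked under 0.5% of cells, the top 6% of cells by score were taken. All passing cells were clustered by Leiden at resolution 1.0 on 30 principal components, 20 neighbours and 2000 variable genes, without batch integration, and the doublets were then removed, which left 132,722 cells. Cd14, C1qa, C1qb and C1qc were left out of the variable genes so that they could not define a cluster. The 54 clusters were named from 16 fixed marker sets. A name needed a mean marker log2 fold of at least 2.0 over the median of the clusters and at least 3 raised markers. A cluster with the markers of a second class (score of 1.5 or more) within a score gap of 1.5 stayed unnamed as mixed. The gap was 2.2 where the doublet share exceeded 0.15, and 1.0 between related classes. Clusters led by genes of another class or low in UMIs also stayed unnamed. In all 19 clusters had no name, and their cells entered no gene test. Classes are called fibroblast-like and so on, because they rest on RNA alone.

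Depth ranged from 43,759,261 to 147,449,040 UMIs per library, and the median per passing cell from 2250 to 13,401. For shares of cells, 95% exact Clopper-Pearson intervals are given, and for UMI counts exact Poisson intervals. A count of 0 was read as allowing up to 3 counts. Intervals and these limits cover counting error only. Shares of cells with a Cd14 or C1qa UMI were taken after thinning every cell to 1000 UMIs, with shallower cells left out.

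For each class, UMI counts were summed per library, and libraries with under 50 cells of the class were left out. This removed the GDB day 0 library (47 cells) from the macrophage tests. The sums were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test) in a model with arm and day as factors. With 12 libraries this model keeps 6 residual degrees of freedom, and it tests an arm difference shared by the days or a day difference shared by the arms. The difference between arms at a single day could not be tested. Genes with a false discovery rate (FDR) under 0.05, given below as adjusted p, are called. Log2 fold changes are given ± SE from the model, and counts per 1,000,000 UMIs are written CPM, with a prior count of 2 where a log2 is taken. Class shares were tested by exact two-sided permutation, with which library is NDB permuted within days (81 assignments, smallest p 0.0123) or which is day 0 within arms (64 assignments, smallest p 0.0156).

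The 20 gene lists fixed with the design were mechanotransduction, contractile, extracellular matrix, matrix proteases and inhibitors, inflammatory mediators, complement and Cd14, interferon response, antigen presentation class II, proliferation, lipid and adipogenic, hypoxia and glycolysis, early stress response, macrophage pro-inflammatory and reparative, keratinocyte basal, differentiation and wound-activated, and carry-over lists for macrophage, keratinocyte and erythrocyte RNA. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Named genes were chosen by a rule: adjusted p under 0.05, the same sign on every day (arm comparisons) or in every arm (day comparisons), a mean log2 CPM of at least 5, and not a mitochondrial, ribosomal protein, Gm-named, Rik-named or Y-linked gene, Xist or Tsix. The rule took the 10 largest rises and falls in fibroblast-like arm comparisons and 6 elsewhere, always Lepr, Cd14, C1qa, C1qb and C1qc, and up to 4 called members per list. In the arm comparisons no gene met its criteria. The arms, tests, lists, filters, this rule and the first set of alternatives below were set before the data were examined.

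The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a stricter cell filter (1000 genes, 2000 UMIs, 10% mitochondrial UMIs), doublets kept, Leiden resolution 2.0 (86 clusters), a term for the Cell Ranger version, no blocking term, leaving out each library, other thinning depths, subtraction of the keratinocyte-like share, and camera with an estimated correlation. Alternatives chosen after seeing the data were the libraries of 1 Cell Ranger version alone, with 1 residual degree of freedom, and keeping doublets and the clusters with fibroblast and macrophage markers as fibroblast-like. The fit was tested on simulated data made from these counts with 200 changed genes. It recovered 74% of 4-fold and 10% of 2-fold changes between GDB and NDB, with 3.4% false calls, and 50% and 1% between day 2 and day 0, with 5.6% false calls. GDB and PDB are both compared with the same NDB libraries, so no overlap or correlation of these comparisons is reported.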

Results

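The data are single-cell RNA counts from unwounded skin and from excisional wounds of C57BL/6 mice. The 12 libraries form 3 arms of 4 libraries each. GDB stands for db/db mice, whose leptin receptor is mutated and which become obese and diabetic. PDB stands for wildtype mice on a high-fat diet, and NDB for wildtype mice with no entry for a special diet. Each arm has unwounded skin at day 0 and wounds at days 2, 7 and 30, with 1 library at each day, so no arm and day is replicated. The series title places the study in mechanotransduction, the conversion of mechanical force into cell signals, and in a group of fibroblasts with Cd14 and C1qa. The comparisons below therefore follow fibroblast-like cells over the days and between the arms, and ask where Cd14 and C1qa were found. At days 0, 2, 7 and 30 the libraries held 51,569,140, 99,719,388, 147,449,040 and 63,101,719 UMIs in GDB, 93,349,776, 58,048,334, 43,759,261 and 77,412,379 in PDB, and 96,112,261, 98,465,047, 67,444,170 and 77,301,874 in NDB. Cells kept numbered 3250, 17,830, 23,049 and 4888 in GDB, 7022, 3460, 4115 and 6133 in PDB, and 12,857, 24,239, 21,447 and 4432 in NDB.

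Skin is rich in keratinocytes, the cells that build the epidermis. A fresh wound fills with monocytes and macrophages, which clear debris, and later with fibroblasts, which lay down new matrix. The share of each cell class in a library was compared between NDB and the other arms and between day 0 and the later days. Keratinocyte-like cells averaged 56.97% of the kept cells at day 0 and 23.81% later, with an exact permutation p of 0.0312 (adjusted p 0.2028 over 13 classes), and day 0 was the highest day in 2 of 3 arms. Monocyte or macrophage-like cells averaged 2.30% at day 0 and 18.71% later (exact p 0.1562, adjusted p 0.4061), and day 0 was the lowest day in 2 of 3 arms. At day 2 they were 48.3% of the cells in GDB, 35.3% in PDB and 30.9% in NDB, and 32.7%, 35.3% and 32.1% with clusters at resolution 2.0. At day 7 they were 23.2%, 10.6% and 4.57%, and at day 30 8.37%, 5.59% and 1.60%. These shares leave out unnamed clusters. In NDB day 7 those held 2691 kept cells with fibroblast and macrophage markers and 916 with keratinocyte and macrophage markers, against 981 macrophage-like cells, and in GDB day 7 they held 212 and 218, against 5338. Averaged over the days, macrophage-like cells were 10.22% in NDB and 16.79% in the other arms, a difference of -6.57 points (exact p 0.1235, adjusted p 0.4014; -3.81 at resolution 2.0, exact p 0.2346, and -12.25 with the stricter cell filter, exact p 0.037), and NDB was lowest at 3 of 4 days. Fibroblast-like cells were 42.5% in GDB, 20.1% in PDB and 41.6% in NDB at day 7. In PDB day 7 unnamed clusters held another 1118 kept cells with endothelial and fibroblast markers, against 829 fibroblast-like cells. Over the days they averaged 24.81% in NDB and 17.66% in the other arms (exact p 0.2469, adjusted p 0.4585), with NDB highest at 2 of 4 days.

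T, NK or innate lymphoid-like cells (lymphocytes) averaged 1.27% in NDB and 3.95% in the other arms. NDB was lowest at 4 of 4 days, a difference of -2.69 points with an exact p of 0.0123, the smallest that 81 assignments can give, and an adjusted p of 0.1599. Unnamed clusters with lymphocyte and macrophage or fibroblast markers held another 283 and 77 kept cells in NDB day 2, against 148 of the class, and 92 and 216 in NDB day 7, against 66, and the share was not tested with them. The same lymphocyte class averaged 5.41% at day 0 and 2.27% later (exact p 0.0312, adjusted p 0.2028), with day 0 highest in 2 of 3 arms. None of the 13 classes passed the adjusted threshold in either exact permutation test, and 2 classes in each had an unadjusted p under 0.05.

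**Figure D1:**
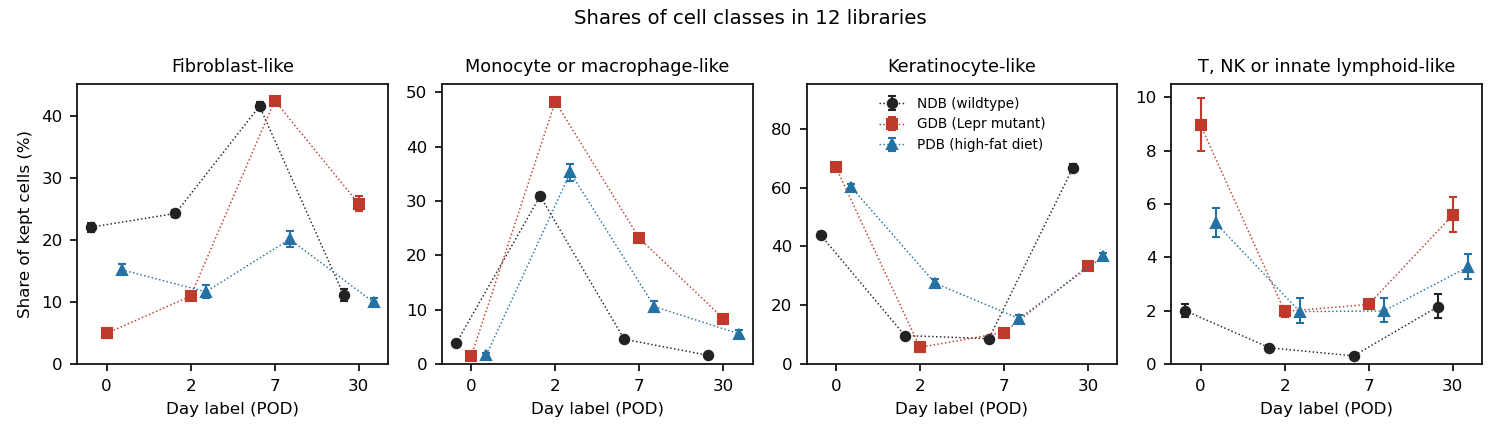
Share of the kept cells (percent) in 4 cell classes against the day, 1 point per library with its 95% exact interval, coloured by arm. Macrophage-like cells peaked at day 2 in each arm, at 48.3% in GDB, 35.3% in PDB and 30.9% in NDB.

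The first gene comparison follows fibroblast-like cells from unwounded skin to the wound. After injury fibroblasts divide, take on contractile fibres and secrete collagens, and over weeks they return toward rest as the scar matures. The camera test called the proliferation and interferon lists up at day 2 and the contractile and matrix lists up at day 7, and macrophage carry-over genes rose with them at both days (medians 3.15 and 2.91). None of these calls held with an estimated correlation (adjusted p from 0.225 to 0.289). Among 16,678 genes tested, 646 rose and 681 fell between day 0 and day 2, 632 rose and 500 fell by day 7, and 19 rose and 5 fell by day 30. DESeq2 called 2895, 2222 and 877 genes. The class spans several clusters, whose mix differed between libraries. At day 0 the largest held 69.6% of the class in NDB (Cell Ranger 6.0.0), led by Coch, Cyp26b1, Cyp2f2 and Pcolce2 among others, while another, led by Igfbp2, Itgbl1 and Robo2 among others, held 68.9% in GDB and 84.1% in PDB (both 7.0.0). All of these genes are among the falls named below. The latter cluster was among the 2 largest in 6 of 7 libraries of 7.0.0 and 0 of 5 of 6.0.0, so the split follows the version. The days differ in version too, with 6.0.0 in 1 of 3 libraries at day 0, 2 of 3 at days 2 and 7, and 0 of 3 at day 30.

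At day 2 the named gene with the largest rise was Serpinb2 (ENSMUSG00000062345, chromosome 1, 107511423 to 107535478), an inhibitor of urokinase. It rose by a log2 fold change of 8.61 ± 0.87 (391-fold, adjusted p 0.00203), in 3 of 3 arms. Sfrp2, a secreted modulator of Wnt signals that marks wound fibroblasts, rose by 4.31 ± 0.64 (19.9-fold, adjusted p 0.00629). Plod2, the enzyme that prepares collagen for stiff cross-links, rose by 3.42 ± 0.38 (adjusted p 0.00205). These 3 stayed called without each library. Among the falls chosen by the rule, C1qtnf3 changed by -4.42 ± 0.47, the growth factor binder Igfbp2 by -4.40 ± 0.53, Itgbl1 by -4.33 ± 0.63, the collagen-binding proteoglycan Fmod by -4.27 ± 0.48 and the basement membrane protein Hmcn1 by -4.14 ± 0.68, with adjusted p values from 0.00205 to 0.00793. Each of these 5 fell in 3 of 3 arms and stayed called without each library. Robo2 also fell (-4.22, adjusted p 0.0159), and was not called without GDB day 0 or day 2, PDB day 0 or day 2, or NDB day 2 (adjusted p 0.05 to 0.0826).

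The proliferation list rose at day 2 by a median of 2.76, with 11 of 15 genes called and 15 when adjusted over the list alone (camera adjusted p 5.71e-17; adjusted p = 0.252 with an estimated correlation). Its member Mcm5, part of the helicase that opens DNA for copying, rose by 3.23 (adjusted p 0.00709). The interferon response list rose by a median of 2.04, with 9 of 15 called and 12 adjusted over the list alone (adjusted p 1.89e-09; 0.252 with an estimated correlation). Irf7, a transcription factor that amplifies interferon signals, rose by 3.04 (adjusted p 0.00462). Hypoxia and glycolysis genes rose by a median of 1.43, with 3 of 12 called and 8 adjusted over the list alone (adjusted p 2.89e-05; 0.252 estimated), among them Hif1a, the oxygen-sensing transcription factor, at 2.23 (adjusted p 0.00671). Inflammatory mediators rose by a median of 2.71, with 2 of 17 called and 3 adjusted over the list alone (adjusted p 2.36e-06; 0.51 estimated). The macrophage carry-over list rose with them, by a median of 3.15, with 6 of 10 called and 7 adjusted over the list alone (adjusted p 6.05e-07; 0.289 estimated). The complement and Cd14 list rose by a median of 0.69, with 4 genes called up and 1 down, and 6 and 1 adjusted over the list alone (adjusted p 0.0312; 0.728 estimated). It lost the call with a term for the Cell Ranger version (0.0902) and without GDB day 0 (0.256), PDB day 2 (0.0747), NDB day 0 (0.0766) or NDB day 2 (0.0668). Cd14, a receptor for bacterial lipid on macrophages, rose by 1.98 ± 0.45 (adjusted p 0.0256) but not without GDB day 0 or day 2 or PDB day 0 or day 2 (0.0712 to 0.0975), and C1qa, a chain of the complement starter C1q, did not pass at 3.10 ± 0.86 (adjusted p 0.0513). C1qb rose by 3.14 and C1qc by 2.85 (adjusted p 0.0325 and 0.0488). C1qb lost its call without any of GDB day 0, 2 or 7, PDB day 0 or 2, or NDB day 2 (0.0516 to 0.105), and C1qc without any library but GDB day 30, PDB day 7 or NDB day 30 (0.0503 to 0.161).

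Mechanotransduction genes did not move as a group at day 2, with a median of 0.06 (adjusted p 0.983). Of the 26, 2 were called up and 4 down (4 and 5 adjusted over the list alone). Actn1, which bundles actin at adhesions, rose by 1.87 (adjusted p 0.0108; 0.0698 without PDB day 0). Among the other lists of day 2, contractile genes had 0 called by edgeR and 2 adjusted over the list alone (camera adjusted p 0.554). Extracellular matrix genes had a median of -0.17 (0.239) with Eln, the gene of elastin, down by -2.73 (adjusted p 0.00598). Proteases and their inhibitors (median 1.06, adjusted p 0.183), lipid and adipogenic genes (0.945), early stress genes (median -0.93, 0.0962), keratinocyte carry-over (0.595) and erythrocyte carry-over (median 2.32, 0.0606) passed no test. Class II antigen presentation had a median of -0.04, a mean of 0.12 and an upward test (0.654). Lepr, the leptin receptor, fell by 2.75 on the log2 scale (adjusted p 0.00709), in 3 of 3 arms. Without 1 library the day 2 count was 440 (GDB day 0), 284 (GDB day 2), 878 (GDB day 7), 216 (PDB day 0), 292 (PDB day 2), 3747 (NDB day 0) or 504 (NDB day 2), and for the other 5 libraries it stayed within 1.5 times of 1327.

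At day 7 Serpinb2 was still raised by 7.50 ± 0.84 (181-fold, adjusted p 0.00157), Sfrp2 by 5.45 ± 0.67 (43.7-fold, 0.00216) and Plod2 by 4.22 ± 0.39 (6e-04). Cthrc1, a secreted protein of wound and scar fibroblasts, rose by 3.97 ± 0.56 (adjusted p 0.00362), Arl4c by 3.56 and the collagen gene Col27a1 by 3.36. The largest falls were in Cyp2f2, a cytochrome (-6.00 ± 0.73, adjusted p 0.00201), Coch, a matrix protein (-5.54), Ism1 (-4.16), Pcolce2, an enhancer of procollagen cleavage (-3.82), and Cyp26b1, which breaks down retinoic acid (-3.75). Each of these 11 changed in the same direction in 3 of 3 arms and stayed called without each library. Contractile genes rose at day 7 by a median of 1.92, with 7 of 12 called and 11 adjusted over the list alone (adjusted p 9.73e-10; 0.225 with an estimated correlation). Acta2, the actin of myofibroblasts, rose by 3.30 ± 0.79 (adjusted p 0.0339) but lost its call without any of GDB day 0 or 7, PDB day 0, 2 or 7, or NDB day 2 or 7 (0.0519 to 0.156), and with the version term (0.0708). Extracellular matrix genes rose by a median of 1.45, with 8 of 20 called up and 1 down, and 14 and 2 adjusted over the list alone (adjusted p 1.38e-08; 0.225 estimated). Fn1, the gene of fibronectin, rose by 2.44 (adjusted p 0.00329), and Postn, a matrix protein of healing wounds, by 2.91 ± 0.47 (adjusted p 0.00722; 0.0519 without PDB day 0). Mmp9, a protease that opens basement membranes, rose by 7.36 (adjusted p 0.00167), and its list of proteases rose by a median of 0.59 with 3 called, and 3 adjusted over the list alone (adjusted p 0.00188; 0.428 estimated).

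Proliferation genes remained up at day 7 by a median of 1.89, with 3 called and 13 adjusted over the list alone (adjusted p 8.84e-10; 0.225 estimated), as did interferon genes at 1.23, with 3 and 7 (0.00178; 0.428 estimated), and hypoxia genes at 1.11, with 3 up and 1 down, and 7 and 1 (0.000109; 0.225 estimated). The macrophage carry-over list rose alongside by 2.91, with 6 of 10 called and 7 adjusted over the list alone (9.43e-08; 0.225 estimated). Complement and Cd14 genes rose by 0.53, with 5 called and 6 adjusted over the list alone (0.0084; 0.428 estimated; 0.126 without GDB day 0). Cd14 rose by 2.52 ± 0.45 (adjusted p 0.00986; 0.0512 without NDB day 7) and C1qa by 3.48 ± 0.86 (adjusted p 0.0373). C1qa lost its call without any of GDB day 0, 2 or 7, PDB day 0, 2 or 7, or NDB day 2 or 7 (0.0505 to 0.169). C1qb rose by 3.09 (0.0367; lost in 8 of 12 such fits, up to 0.168 without NDB day 7) and C1qc by 3.09 (0.0403; lost in 7, up to 0.195 without NDB day 7). Class II genes rose by a median of 0.77 with 1 of 6 called, and 1 adjusted over the list alone (0.0262; 0.409 estimated), and not without GDB day 0 (0.126), GDB day 7 (0.0652), NDB day 0 (0.235) or NDB day 7 (0.0733). Inflammatory mediators rose by 1.48 with 2 called, and 2 adjusted over the list alone (0.0133; 0.51 estimated), but not without GDB day 0 (0.197) or NDB day 7 (0.244). Early stress genes fell, with a median of -0.93 and no member called (0.0084; 0.51 estimated), but not without PDB day 7 (0.412) or NDB day 0 (0.235). The erythrocyte carry-over list rose by 3.04 (0.0164; 0.428 estimated; 0.126 without GDB day 0). Mechanotransduction genes again passed no group test (median 0.13, adjusted p 0.324), with 3 called up and 1 down, and 3 and 2 adjusted over the list alone, and Actn1 was up by 2.44 (adjusted p 0.00334). Lipid genes passed no test (0.39), and the keratinocyte carry-over list had a median of -0.15, a mean of 0.07 and a downward test (0.887). Lepr fell by 3.53 on the log2 scale (adjusted p 0.00222). The complement (0.0521), class II (0.107), inflammatory (0.349) and erythrocyte (0.0748) lists lost their day 7 calls with the version term, class II and erythrocyte genes also with doublets kept (0.344 and 0.274). The day 7 count of 1132 became 428 (without GDB day 0), 450 (GDB day 7), 239 (PDB day 0), 739 (PDB day 2), 384 (PDB day 7), 2302 (NDB day 0), 303 (NDB day 7) or 1703 (NDB day 30).

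At day 30 edgeR called 24 genes, against 877 by DESeq2 and 542 with no low-count filter. Mdk, a growth factor of embryonic and repairing tissue, rose by 2.32 ± 0.31 (4.98-fold, adjusted p 0.0291), and Il1r2, a decoy receptor for interleukin 1, fell by 2.33 on the log2 scale (adjusted p 0.0331), each in 3 of 3 arms. Mdk lost its call without any of GDB day 0, 7 or 30, PDB day 0 or 2, or NDB day 2 or 7 (0.0531 to 0.219), and Il1r2 without those or NDB day 0 (0.0615 to 0.172). Extracellular matrix genes stayed up by a median of 0.81, with 0 called by edgeR and 3 adjusted over the list alone (camera adjusted p 1.59e-05; 0.788 estimated). Early stress genes were down by a median of -1.52, with 2 called adjusted over the list alone (1.5e-07; 0.788 estimated), and proliferation genes by -0.77 (0.00171; 0.788 estimated), though not with the version term (0.262), with doublets kept (0.067), or without NDB day 0 (0.969, upward) or NDB day 30 (0.281). Complement and Cd14 genes were down by a median of -0.09 and a mean of -0.40 (0.0414; 0.788 estimated). That call was lost with the version term (0.262), with doublets kept (0.0837), and without GDB day 7 (0.0545), PDB day 0 (0.29), PDB day 7 (0.0567), PDB day 30 (0.0976), NDB day 0 (0.137), NDB day 2 (0.0515) or NDB day 30 (0.585). Changes of Cd14 (-0.08), C1qa (0.07), C1qb (0.13), C1qc (0.40) and Lepr (-1.73) passed no test, with adjusted p values of 0.953, 0.983, 0.957, 0.846 and 0.104. The remaining lists passed no test: mechanotransduction (median 0.16, adjusted p 0.888), contractile (0.41, 0.17), proteases (0.41, 0.206), inflammatory mediators (-0.49, 0.107), class II (-0.77, 0.263), lipid (-0.33, 0.262), hypoxia (-0.22, 0.259) and erythrocyte carry-over (-0.77, 0.798). Medians and tests differed in sign for interferon genes (0.07, mean 0.04, downward test, 0.72), and medians and means for macrophage carry-over (-0.04 and 0.09, upward test, 0.848) and keratinocyte carry-over (-0.03 and 0.01, downward test, 0.888). The count of 24 was 5, 12, 3 and 0 without GDB day 0, 2, 7 and 30, 0, 2 and 327 without PDB day 0, 2 and 30, and 4, 3, 2 and 371 without NDB day 0, 2, 7 and 30.

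**Figure D2:**
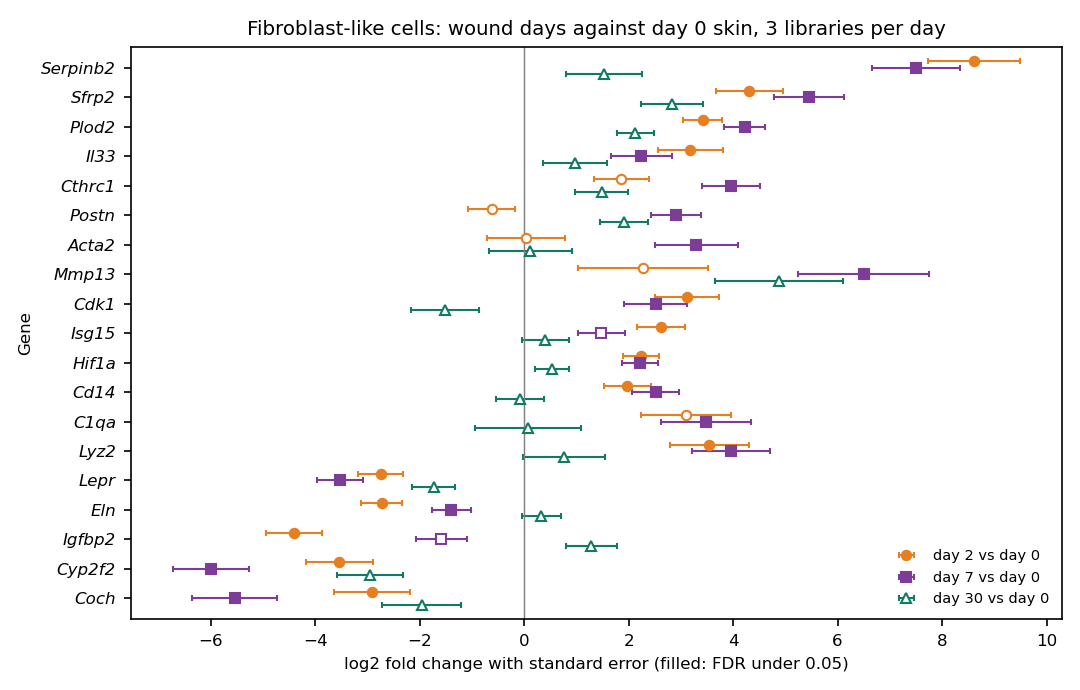
Log2 fold change with standard error of selected genes in fibroblast-like cells at days 2, 7 and 30 against day 0, filled where the adjusted p was under 0.05. Serpinb2 was up by 8.61 at day 2 and 7.50 at day 7, while Lepr was down at -2.75 and -3.53.

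The comparison of GDB with NDB asks how fibroblast-like cells of skin and wound differ in db/db mice. Leptin is a hormone of fat tissue, and its receptor acts in dermal fibroblasts as well as in the brain. Interferon-induced genes are an antiviral programme that injury also switches on. Complement factors, made by resting dermal fibroblasts, mark microbes and debris for removal. The camera test called the interferon, complement and class II lists lower in GDB, though not with an estimated correlation (adjusted p = 0.156 for each), and edgeR called Lepr lower. The 2 arms also differed in the clusters that make up the class. At day 7 the largest held 39.2% of it in GDB, led by Sfrp2 and Mfap5, and 52.1% in NDB, led by H19 and Col12a1.

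Among 16,678 genes edgeR called 1 higher and 4 lower in GDB, with 985 at an unadjusted p under 0.05 and 51 called by DESeq2. Apart from Lepr these genes were chosen after their values were seen, and each had the same sign at 4 of 4 days. Lepr (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352, GRCm38) changed by -2.91 ± 0.37 (7.49-fold lower, adjusted p 0.0364). Its level in unwounded skin was 32.8 CPM in GDB (24.3 to 43.2) and 70.1 in NDB (66.0 to 74.5). These libraries differ in Cell Ranger version, while those of days 2, 7 and 30, given in the last part, match. The call was lost without any library but PDB day 7, PDB day 30 or NDB day 0 (adjusted p 0.0594 without PDB day 0 to 0.286 without GDB day 2). Cfd (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), the protease factor D that drives the alternative complement pathway and is secreted by fat cells, changed by -5.99 ± 0.62 (adjusted p 0.00869). There were 7 Cfd UMIs among 94,086,085 from GDB and 472 among 67,728,195 from NDB, a ratio of 0.0107 (0.00427 to 0.0222). Its adjusted p was 0.0527 and 0.0789 without GDB day 0 and 30, 0.0594 without PDB day 0, 0.0822 and 0.131 without NDB day 0 and 2, and 0.342 with the stricter cell filter. Greb1 (ENSMUSG00000036523, chromosome 12, 16670615 to 16800886), a hormone-regulated gene, changed by -4.40 ± 0.50 (adjusted p 0.0137). Its adjusted p was 0.0799 and 0.14 without GDB day 0 and 2, 0.0594 without PDB day 0, and 0.0504 and 0.131 without NDB day 0 and 2. Ptpn5 (ENSMUSG00000030854, chromosome 7, 47077795 to 47133684), a tyrosine phosphatase, changed by -4.43 ± 0.60 (adjusted p 0.0458) and lost its call without any library but PDB day 30 (0.0906 to 0.439). The transcript AA465934 (ENSMUSG00000093483, chromosome 11, 83291699 to 83294632) was 53.4-fold higher (5.74 ± 0.47, adjusted p 0.00153) and stayed called without each library (highest 0.0123). By summed UMIs it was also higher in GDB macrophage-like (28.6-fold) and keratinocyte-like cells (16.7-fold), so the rise was not confined to fibroblast-like cells. The count of 5 became 1, 2, 3 and 2 without GDB day 0, 2, 7 and 30, 1 and 3 without PDB day 0 and 2, and 3, 1, 3 and 3 without NDB day 0, 2, 7 and 30.

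The interferon response list fell in GDB by a median of 1.07 on the log2 scale (camera adjusted p 1.4e-13; adjusted p = 0.156 with an estimated correlation). edgeR called 0 of its 15 genes over all genes tested, and 9 adjusted over the list alone. Among these were Ifit1 (-1.66), Ifi27l2a (-1.44), Oasl2 (-1.22), Bst2 (-1.07) and Irf7 (-1.02), each lower at 4 of 4 days and chosen after their values were seen. The mean of the list relative to NDB of the same day was -1.5 at day 0, -1.88 at day 2, -0.72 at day 7 and -0.18 at day 30, with 15, 15, 14 and 10 of the 15 genes lower. In CPM, Irf7 was 54.0 in GDB and 209 in NDB at day 2, and 36.4 against 63.3 at day 7. Days 2, 7 and 30 each lie within 1 Cell Ranger version in these arms, and day 0 does not. Complement and Cd14 genes fell by a median of 0.66, with Cfd called and 3 of 14 adjusted over the list alone (adjusted p 5.88e-10; 0.156 estimated). Class II genes, which present antigen, fell by 0.94, with 2 of 6 adjusted over the list alone (0.000281; 0.156 estimated). These 3 lists kept their calls without each library. Macrophage carry-over genes were lower without passing (-0.44, adjusted p 0.136). The keratinocyte carry-over list fell with these lists, by 1.15, with 3 adjusted over the list alone (3.12e-06; 0.202 estimated), and the erythrocyte list rose by 2.86, with 1 adjusted over the list alone (0.00169; 0.474 estimated), but not without GDB day 2 (0.138) or NDB day 30 (0.0992). Proliferation genes fell by 0.33 (0.00151; 0.781 estimated), though not with the version term (0.278) or without GDB day 0 (0.161) or NDB day 0 (0.99).

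Mechanotransduction genes did not differ as a group (median 0.02, adjusted p 0.478), nor did contractile genes (-0.19, 0.304), proteases (0.09, 0.644), lipid genes (0.17, 0.883), hypoxia genes (-0.03, 0.883) or early stress genes (0.21, 0.304). Extracellular matrix genes had a median of 0.08, a mean of -0.02 and an upward test (0.881), and inflammatory mediators a median of 0.03, a mean of -0.22 and an upward test (0.868). Cd14 (-0.21 ± 0.37), C1qa (-0.83 ± 0.69), C1qb (-0.24) and C1qc (-0.16) passed no test, with adjusted p values of 0.962, 0.929, 0.978 and 0.987.

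**Figure D3:**
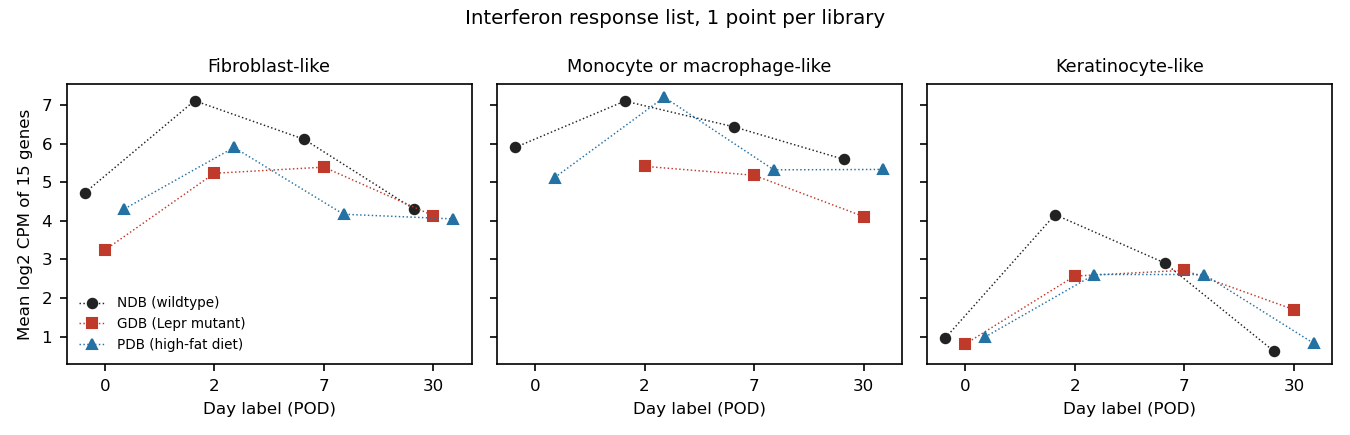
Mean log2 CPM of the 15 interferon response genes against the day in fibroblast-like, macrophage-like and keratinocyte-like cells, 1 point per library, coloured by arm. In fibroblast-like cells GDB lay -1.88 from NDB at day 2 and -0.18 at day 30.

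The comparison of PDB with NDB asks what a high-fat diet changes in fibroblast-like cells with an intact leptin receptor. Obesity alters the fat beneath the dermis and the signals fibroblasts receive from it. The PDB libraries come from the later Cell Ranger version, and at days 0, 2 and 7 their NDB partners do not. edgeR called 2 genes higher and 2 lower, with 2690 at an unadjusted p under 0.05 and 972 by DESeq2 (779 higher, 193 lower). With a term for the version edgeR called 0, with 1002 at an unadjusted p under 0.05.

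The 4 genes did not meet the criteria for named genes and were chosen after their values were seen. Each had the same sign at 4 of 4 days. Cfd was the strongest, at -7.94 ± 0.76 (adjusted p 0.00761), with 1 UMI among 37,817,434, a ratio to NDB of 0.00379 (9.59e-05 to 0.0212). Chrdl1, a secreted antagonist of bone morphogenetic proteins, changed by -1.89 ± 0.25 (3.71-fold lower, adjusted p 0.0457). It stood at 12.8, 35.5, 15.4 and 8.22 CPM in PDB at days 0, 2, 7 and 30, and at 34.0, 123, 59.7 and 31.9 in NDB. Cadm2 (chromosome 16, 66655421 to 67620908), a cell adhesion gene with long introns, was 10.5-fold higher (3.39 ± 0.41, adjusted p 0.0419), and the transcript 6030407O03Rik rose by 4.62 ± 0.61 (0.0457). With the version term their changes were -7.36, -1.45, 2.27 and 3.40, a median of 0.75 of the changes without it, and each had an adjusted p of 0.809. Cfd lost its call without PDB day 0 (0.175), PDB day 7 (0.0768), NDB day 0 (0.183) or NDB day 2 (0.17). The calls of Chrdl1 and Cadm2 were lost without any of GDB day 2 or 7, PDB day 0 or 7, or NDB day 0, 2 or 7, Cadm2 also without GDB day 0 and Chrdl1 without PDB day 2 (0.0691 to 0.344). That of 6030407O03Rik was lost without any library but GDB day 30 or PDB day 30 (0.0675 to 0.344). The count of 4 became 2, 1, 1 and 32 without GDB day 0, 2, 7 and 30, 0, 2, 0 and 867 without PDB day 0, 2, 7 and 30, and 0, 0, 1 and 16 without NDB day 0, 2, 7 and 30.

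Extracellular matrix genes fell in PDB by a median of 0.60, with 2 of 20 adjusted over the list alone, Col14a1 (-1.23) and Fn1 (-1.05), both lower at 4 of 4 days (camera adjusted p 9.15e-07; adjusted p = 0.265 with an estimated correlation). The arms differed in the clusters of the class. At day 7 the one led by H19 and Col12a1 held 7.8% in PDB and 52.1% in NDB, and one led by Sdk1 and Pcsk5 held 72.0% in PDB. The latter was among the 3 largest in 7 of 7 libraries of 7.0.0 and 0 of 5 of 6.0.0, and at day 30, within 7.0.0, it held 34.1% in PDB and 43.4% in NDB. Complement and Cd14 genes fell by 0.86, with 1 called and 6 adjusted over the list alone (2.16e-08; 0.265 estimated), and class II genes by 1.70, with 4 of 6 adjusted over the list alone (0.000253; 0.265 estimated). Interferon genes fell by 0.86, with 0 called by edgeR over all genes or over the list alone (9.1e-07; 0.265 estimated). Macrophage carry-over genes fell with them by 1.92, with 5 adjusted over the list alone (9.1e-07; 0.265 estimated), and keratinocyte carry-over genes by 1.14, with 1 (0.000251; 0.268 estimated). Both carry-over lists turned upward with the version term (adjusted p 0.691 and 0.753). These 6 calls held without each library. Cd14 (-0.62, adjusted p 0.443), C1qa (-3.14, 0.113), C1qb (-1.81, 0.209), C1qc (-2.32, 0.141) and Lepr (-0.87, 0.252) passed no test. No call was made for mechanotransduction (0.03, 0.874), contractile genes (0.19, 0.921), proteases (-0.35, 0.0909), inflammatory mediators (-0.79, 0.259), proliferation (-0.24, 0.561), lipid genes (-0.42, 0.0803), hypoxia (-0.31, 0.165), early stress (-0.48, 0.129) or erythrocyte carry-over (-1.33, 0.312).

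The comparison of PDB with GDB sets the diet beside the mutation. Both models bring obesity, one through feeding and the other through lost leptin signals. At days 0 and 30 both arms come from the same Cell Ranger version. edgeR called 1 gene higher and 1 lower, both chosen after their values were seen, with 1771 at an unadjusted p under 0.05 and 251 by DESeq2. Cadm2 was 27.1-fold higher in PDB (4.76 ± 0.46) and AA465934 35.2-fold lower (-5.14 ± 0.46), each with an adjusted p of 0.00418 and the same sign at 4 of 4 days. With the version term their adjusted p values were 0.0353 and 0.0478, and Cadm2 had 0.0659 without GDB day 7. The count of 2 became 1 without GDB day 7, 202 without PDB day 30 and 4 without NDB day 30.

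Extracellular matrix genes were lower in PDB than in GDB by a median of -0.80, with 4 adjusted over the list alone, Col14a1 (-0.95), Fn1 (-1.10), Eln (-1.17) and Col6a2 (-1.10), each lower at 4 of 4 days (camera adjusted p 9.95e-09; adjusted p = 0.535 with an estimated correlation). At day 7 the cluster led by H19 and Col12a1 held 7.8% of the class in PDB (7.0.0) and 37.4% in GDB (6.0.0). The list kept its call without each library. Proteases (-0.33, 1 adjusted over the list alone, adjusted p 0.0112; 0.764 estimated) lost theirs without GDB day 30 (0.261) or PDB day 7 (0.194). Lipid genes (-0.26, 0.0344; 0.667 estimated) lost it without GDB day 0 (0.0588), PDB day 0 (0.131) or PDB day 7 (0.168), and early stress genes (-0.66, 0.00401; 0.764 estimated) without PDB day 7 (0.612). Macrophage carry-over genes were lower with these lists (-1.40, 4 adjusted over the list alone, 3.66e-05; 0.635 estimated), as were erythrocyte genes (-4.20, 5 adjusted over the list alone, 7.26e-05; 0.635 estimated). These 5 lists were not called with the version term (0.208 to 0.853), and early stress and macrophage carry-over genes turned upward. Lists without a call were mechanotransduction (-0.03, 0.65), contractile (0.41, 0.277), inflammatory mediators (-0.63, 0.11), complement and Cd14 (-0.16, 0.169), interferon (0.18, 0.65), class II (-0.71, 0.257), proliferation (0.33, 0.051), hypoxia (-0.25, 0.147) and keratinocyte carry-over (-0.12, 0.715). Lepr (2.03, adjusted p 0.27), Cd14 (-0.40, 0.725), C1qa (-2.30, 0.382), C1qb (-1.57, 0.449) and C1qc (-2.15, 0.374) passed no test.

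The title genes Cd14 and C1qa are typical of macrophages. With every cell thinned to 1000 UMIs, cells holding UMIs of both genes made up a mean of 0.083% of fibroblast-like cells in NDB and 0.032% in the other arms (exact permutation p 0.2222, adjusted p 0.3333), with NDB highest at 2 of 4 days. For Cd14 alone the means were 1.059% and 0.757% (exact p 0.4815, adjusted p 0.4815, NDB highest at 1 of 4 days), and for C1qa alone 1.668% and 0.624% (exact p 0.0494, adjusted p 0.1482, NDB highest at 3 of 4 days). The C1qa difference of 1.044 points had an exact p of 0.0741, 0.1852 and 0.2222 without day 0, 2 or 7. After the keratinocyte-like share was subtracted it was 0.004 (exact p 1.0), and the difference for both genes -0.119 (exact p 0.2222). The highest fibroblast-like share of both genes was in NDB day 7, 22 of 8928 cells or 0.246% (0.154 to 0.373) at a median depth of 2325 UMIs. Keratinocyte-like cells of that library had 12 of 1851 or 0.648% (0.335 to 1.13) at a median of 2511 UMIs, and endothelial-like cells 4.33% (3.22 to 5.68) at 1768. Keratinocyte-like cells may be no clean blank for Cd14, in PDB at 395 UMIs to 146 of C1qa (14,781 to 21,040 in macrophage-like cells). In 6 of 12 libraries no fibroblast-like cell held both genes. In the other 6 the fibroblast-like share was under the endothelial-like share in 5 and under the keratinocyte-like share in 3, mostly on counts of 1 to 3 cells. Over the libraries the median share was 0.016% in fibroblast-like and 18.0% in macrophage-like cells. In GDB day 0, 0 of 161 thinned fibroblast-like cells showed both genes (exact upper bound 2.265%), and a cell with few copies can show none at this depth.

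**Figure D4:**
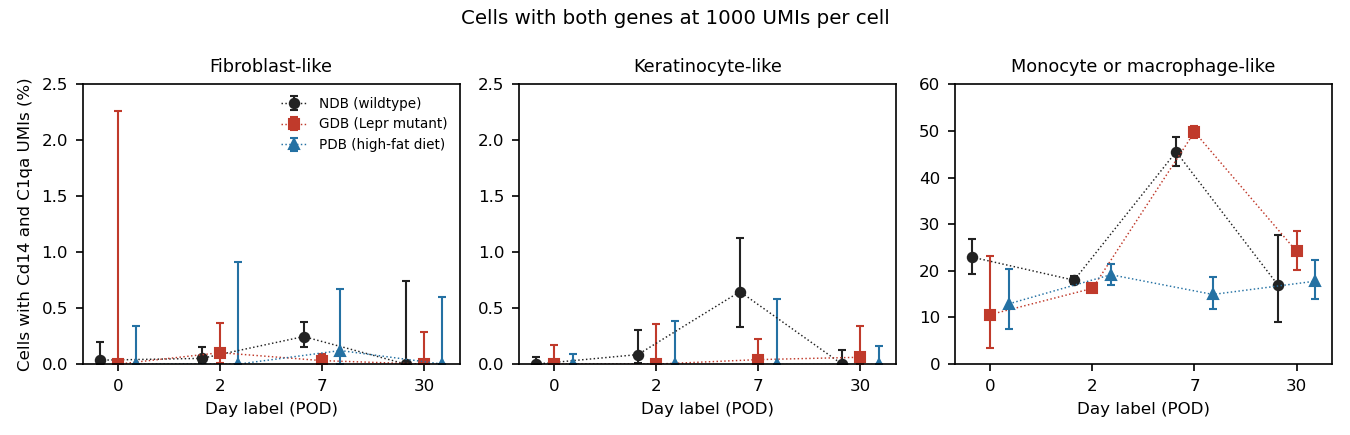
Cells with UMIs of both Cd14 and C1qa (percent) at 1000 UMIs per cell against the day, 1 point per library with its 95% exact interval, on a wider scale for macrophage-like cells. At NDB day 7 the share was 0.246% in fibroblast-like and 0.648% in keratinocyte-like cells.

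Macrophages were compared next, because they steer the passage from inflammation to repair. Interferon-induced genes and class II antigen presentation mark their activation. The camera test called both lists lower in GDB, and with an estimated correlation the interferon list (adjusted p 0.0306) but not class II (0.414). The 2 arms differed in the clusters of the class. At day 7 the one led by Pf4 and Ccl6 held 46.7% in GDB and 72.3% in NDB. The fit covered 11 libraries and 11,689 genes. edgeR called 0 genes between GDB and NDB, with 772 at an unadjusted p under 0.05 and 99 by DESeq2.

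The interferon list fell in GDB macrophage-like cells by a median of 1.51 on the log2 scale, with 11 of 15 genes adjusted over the list alone (camera adjusted p 1.61e-26; 0.0306 with an estimated correlation). It is the one camera call of the 3 classes that held with an estimated correlation. Members lower at each of the 3 days shared by both arms included Oasl2 (-1.87), Ifit2 (-2.15), Ifit3 (-2.08), Ifit1 (-2.00) and Irf7 (-1.51). Class II genes fell by 1.39, with 5 of 7 adjusted over the list alone, among them H2-Ab1 (-1.60) and Cd74 (-1.39) (adjusted p 1.34e-07; 0.414 estimated). Both calls held without each library. Keratinocyte carry-over genes fell with them (-0.95, 0.000439; 0.54 estimated). Hypoxia genes were higher by 0.28 (0.0236; 0.54 estimated), though not without GDB day 7 (0.102), GDB day 30 (0.188) or NDB day 30 (0.624). The pro-inflammatory (0.26, 0.225) and reparative (0.33, 0.0781) lists, complement and Cd14 (-0.22, 0.0908), inflammatory mediators (0.26, 0.845), proliferation (0.624), lipid genes (0.31, 0.135) and erythrocyte carry-over (1.94, 0.0908) passed no test. Cd14 (0.84) and C1qa (-0.34) each had an adjusted p of 0.813.

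Between PDB and NDB macrophage-like cells edgeR called 1 gene, Serpinh1, a chaperone for collagen, lower by -2.77 ± 0.28 (6.81-fold, adjusted p 0.0395), at 4 of 4 days and named after its value was seen. DESeq2 called 701, and 2063 had an unadjusted p under 0.05. With the version term Serpinh1 was at -2.31 (adjusted p 0.818), and it lost its call without any of GDB day 7, PDB day 0, 2 or 7, or the NDB libraries (0.0503 to 0.291). The count was 5 without GDB day 2, 51 without GDB day 30, 1306 without PDB day 30 and 0 without any of the other 8. The clusters of the class follow the Cell Ranger version: the one led by Pid1 and Lrmda held 78.7 to 94.3% in the libraries of 7.0.0 and at most 0.4% in those of 6.0.0. At day 30, within 7.0.0, it held 89.5% in PDB and 91.5% in NDB. Complement and Cd14 genes were lower by -0.72, with 2 adjusted over the list alone (0.000307; 0.527 estimated), and interferon genes by -0.45, with 1 (0.00213; 0.527 estimated; 0.0685 without PDB day 7; 0.115 with the version term). Keratinocyte carry-over (-1.52, 0.000167; 0.527 estimated) and erythrocyte carry-over (-5.36, 2 adjusted over the list alone, 0.0218; 0.702 estimated) were lower too, the latter not without PDB day 2 (0.22), PDB day 7 (0.118) or NDB day 7 (0.0613). The keratinocyte list turned upward (0.49) with the version term, and the erythrocyte list was called upward (0.000269). The pro-inflammatory (0.98, 0.194), reparative (-0.01, 0.194), class II (0.48, 0.171), proliferation (-0.13, 0.46), lipid (0.23, 0.702) and hypoxia (0.14, 0.295) lists passed no test. Inflammatory mediators had a median of 0.09, a mean of -0.01 and a downward test (0.496). Cd14 (0.68, adjusted p 0.532) and C1qa (-0.62, 0.189) were not called.

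Over the days, monocytes recruited to a wound give way to settled macrophages. Here the camera test called the interferon list up and class II down at day 2, and class II up and inflammatory mediators down at day 30. None of these calls held with an estimated correlation (adjusted p from 0.157 to 0.419). The version, which the clusters follow, differs between the days, with day 30 wholly in 7.0.0. Within 6.0.0 the cluster led by Pf4 held 31.6% in NDB at day 0 and 85.8% at day 2. For days 2, 7 and 30 against day 0 edgeR called 0 single genes, with 1298, 1013 and 2075 at an unadjusted p under 0.05 and 299, 153 and 716 by DESeq2. At day 2 the interferon list rose by 1.35, with 9 of 15 adjusted over the list alone (3.29e-13; 0.157 estimated), and class II fell by 1.56, with 4 of 7 (1.63e-06; 0.351 estimated). Complement and Cd14 genes fell by 0.70 (0.00196; 0.351 estimated), and keratinocyte carry-over by 1.06 (0.000625; 0.351 estimated). Hypoxia genes rose by 0.55 (0.00675; 0.351 estimated), but not without PDB day 0 (0.55) or PDB day 2 (0.0851). Proliferation genes fell by 0.73 (0.026; 0.351 estimated), but not without GDB day 2 (0.112), GDB day 30 (0.0849), PDB day 0 (0.174) or PDB day 2 (0.0851). The erythrocyte list rose by 6.68 (0.00196; 0.351 estimated; 0.0689 without NDB day 0). Median and test differed in sign for the pro-inflammatory (0.22, mean -0.22, 0.369), reparative (0.40, mean -0.03, 0.254) and inflammatory mediator lists (0.07, mean -0.09, 0.621), and lipid genes passed no test (0.56, 0.369).

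At day 7 hypoxia genes rose by 0.78, with 4 of 12 adjusted over the list alone (2.03e-05), interferon genes by 0.77 (0.00364), lipid genes by 0.60 (0.018) and erythrocyte genes by 5.87 (0.00364), while keratinocyte carry-over fell by 1.01 (0.00364). Each had an adjusted p of 0.497 with an estimated correlation. Without PDB day 0 the hypoxia and interferon lists had 0.11 and lipid genes 0.13, lipid genes also 0.0578 without PDB day 30, 0.0842 without NDB day 7 and 0.0531 with the version term. Without NDB day 0 both carry-over lists had 0.0911, and keratinocyte genes 0.228 without PDB day 7. The pro-inflammatory and inflammatory mediator lists (0.165 each), reparative genes (0.732), and complement, class II and proliferation (0.961 each) passed no test. At day 30 class II rose by 1.73, with 7 of 7 adjusted over the list alone (0.000126; 0.419 estimated; 0.476 with the version term), and inflammatory mediators fell by 2.28 (4.37e-06; 0.419 estimated). Both stayed called without each library. Pro-inflammatory genes were down by -1.14 (0.00575; 0.608 estimated), but not without PDB day 0 (0.11), PDB day 30 (0.126) or NDB day 30 (0.102). Reparative genes fell by 0.50, with 3 adjusted over the list alone (0.00293; 0.419 estimated; 0.115 without NDB day 30; 0.135 with the version term), and complement genes by 0.73 (0.00575; 0.419 estimated; 0.05 without PDB day 30). Hypoxia genes fell by 0.62 (0.0403; 0.608 estimated), but not with the version term (0.372) or without GDB day 7 (0.0596), NDB day 0 (0.876) or NDB day 30 (0.648). Interferon genes had a median of 0.05, a mean of -0.02 and a downward test (0.682), and erythrocyte genes passed no test (0.929). Day 2 had 100 calls without PDB day 30, 1 without NDB day 0 and 62 without NDB day 30, day 7 had 3 without NDB day 2, and day 30 had 865 without PDB day 30 and 4 without NDB day 30.

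Keratinocytes close a wound by dividing and moving across it. The camera test called their proliferation list lower in GDB than in NDB, though not with an estimated correlation (adjusted p = 0.464). Among 17,388 genes edgeR called 0 between GDB and NDB, with 980 at an unadjusted p under 0.05 and 65 by DESeq2, and 1 without GDB day 2, GDB day 30 or NDB day 30. The proliferation list fell by 0.61, with Ccnb1 (-0.92) and Top2a (-0.95) passing adjusted over the list alone and both lower at 4 of 4 days (camera adjusted p 9.53e-08; adjusted p = 0.464 with an estimated correlation). It kept its call without each library. The 2 arms also differed in the clusters of the class at days 2 and 7. Macrophage carry-over genes fell by 0.79 (0.0114; 0.874 estimated), but not with the version term (0.952) or without GDB day 0 (0.982), NDB day 0 (0.0872), NDB day 2 (0.269) or NDB day 7 (0.171). The erythrocyte list rose by 1.68 (0.00116; 0.605 estimated), but not without GDB day 2 (0.224) or NDB day 30 (0.208). Interferon (-0.21, 0.355), differentiation (-0.23, 0.355), wound-activated (-0.67, 0.17) and early stress genes (0.23, 0.0574) passed no test. Median and test differed in sign for basal genes (-0.12, mean 0.06, 0.716) and hypoxia genes (-0.12, mean 0.01, 0.716).

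Between PDB and NDB keratinocyte-like cells edgeR called 0 genes, with 2110 at an unadjusted p under 0.05 and 671 by DESeq2, and 1 without GDB day 0, 11 without PDB day 30 and 404 without NDB day 30. Early stress genes fell by 0.71 (0.00139; 0.296 without PDB day 7), interferon genes by 0.65 (0.031), differentiation genes, which build the outer barrier, by 0.51 (0.0443) and proliferation genes by 0.30 (0.0443). Macrophage carry-over genes fell with them by 1.65 (8.71e-07). Each had an adjusted p of 0.611 with an estimated correlation. The arms differed in the clusters of the class. At day 30, within 7.0.0, the one led by Gm973 held 36.2% in PDB and was not among the 3 largest in NDB. The one led by Krt1 held 24.7% in PDB and 24.4% in NDB. With the version term early stress and differentiation genes were called up (0.0114 and 0.0153), and interferon (0.368) and macrophage carry-over genes (0.292, upward) were not called. Differentiation lost its call without PDB day 7 (0.508), NDB day 0 (0.336), NDB day 2 (0.323) or NDB day 7 (0.0936). Interferon lost it without PDB day 2 (0.144), PDB day 30 (0.077) or NDB day 2 (0.652), and proliferation with doublets kept (0.058) and without PDB day 0 (0.22), PDB day 30 (0.428), NDB day 0 (0.166) or NDB day 30 (0.21). Basal genes (-0.06, 0.648), hypoxia genes (0.17, 0.755) and erythrocyte carry-over (-1.28, 0.0558) passed no test, and wound-activated genes had a median of 0.13, a mean of -0.08 and an upward test (0.648).

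The last comparison asks how far fibroblast-like cells of an arm moved over the days. The title contrasts healing of healthy wounds over time, so the distance between days of 1 arm was the root mean square difference of log2 CPM. Over 16,678 genes the mean distance was 1.24 in NDB (0.716 to 1.63), 1.54 in GDB (0.885 to 1.83) and 1.27 in PDB (0.981 to 1.42). The ranges overlap, the 6 pairs of days in an arm share libraries, and no test was made. GDB and NDB span both Cell Ranger versions while PDB lies in 1.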

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

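The 3 tests of the cells that carry both fibroblast and macrophage markers and the fit to the 7.0.0 libraries alone were chosen after the results they address were seen, as was the minimum of 10 such cells for the free RNA test, and the other tests in this part before. Each arm and day has 1 library, so no library could be set against replicates of its own group, and whether the effect of wounding differs between the arms was not tested. The shares in this paragraph are of clusters with the markers of 2 cell classes, which are left out of the named classes. Each made up at least 5% of the passing cells of a library, and its interval lay above that of day 0 in the same arm. Cells with fibroblast and macrophage markers were 6.26% of GDB day 7, 11.3% of NDB day 2 and 12.6% of NDB day 7. In GDB day 2, cells with macrophage and neutrophil markers were 9.52%, and cells with dendritic or Langerhans and macrophage markers 6.72%. In NDB day 2, cells with dendritic or Langerhans and macrophage markers were 5.67%, and cells with keratinocyte and macrophage markers 5.44%. Cells with endothelial and fibroblast markers were 26.7% of PDB day 7, and cells with fibroblast and keratinocyte markers 6.40% of NDB day 7. No explanation was tested for the pairs other than fibroblast and macrophage.

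The first pattern is the cluster of 8614 cells with fibroblast and macrophage markers. In 4 of 4 libraries with at least 300 such cells Cd14 reached 0.27, 0.27, 0.33 and 0.29 of macrophage level. C1qa reached 0.30, 0.29, 0.26 and 0.21, and both lay between the 5th and 95th percentile of the other macrophage genes. A fibroblast state raising all of these together would give such shares and stays open. So does one with Cd14 and C1qa raised beyond the others, as they could define no cluster and its cells may lie elsewhere. RNA of a fibroblast and a macrophage in 1 droplet passed its test in the same 4 libraries, with weights summing to 0.97 to 1.0. UMIs per cell were 10,686, 6881, 3630 and 2499, against 7889, 5496, 2958 and 2325 in fibroblast-like cells. Scrublet marked 54.8, 87.4 and 76.8% of the cluster as doublets in 3 of them. NDB day 7 stays open: 6.2% were marked where 6% was imposed, and UMIs rose less than the 1372 of macrophage-like cells. Chance pairing in droplets also passed its test, with barcodes under the cell filter counted as single cells. Fibroblasts paired with macrophages at a median of 0.875 times their rate with keratinocytes, and in 0 libraries at over 2 times. Without those barcodes the ratios were 1.24, 0.99, 0.95 and 3.71, the last in NDB day 7, so pairs formed in the tissue may add to the chance pairs there, and a biological difference between arms or days was not tested.

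The second pattern is the small share of fibroblast-like cells with UMIs of both Cd14 and C1qa. Free RNA in the droplets stays open: with cells thinned to 1000 UMIs, in 0 of 12 libraries did the fibroblast-like share exceed 2 times the keratinocyte-like share beyond their bounds, but 6 of the 12 had no such fibroblast-like cell and in 1, NDB day 7, the 2 classes held at least 10 such cells together. Doublets with macrophages, or macrophage RNA in fibroblast-like cells, passed their test, because cells with both genes before thinning carried macrophage genes at a median of 6.3 times the level of other fibroblast-like cells over genes and libraries (library medians 5.1 to 8.77 in the 4 with at least 10 such cells, 248 cells of 34,257 in all 12). Both sources may act, and expression of the pair or of Cd14 alone by a fibroblast was not tested apart from them. Relative to C1qa, Cd14 was higher in fibroblast-like than macrophage-like cells of each arm (in PDB 319 to 72 UMIs, against 14,781 to 21,040). A biological difference between the arms was not tested beyond the permutation tests of the shares.

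The third pattern is the genes called between PDB and NDB in fibroblast-like cells. With a term for the Cell Ranger version or hashtag batch 0 of the 4 calls were left, but the changes kept a median of 0.75 of their size, Cfd going from -7.94 ± 0.76 to -7.36 ± 1.29 and Cadm2 from 3.39 ± 0.41 to 2.27 ± 0.47, so the calls ended with a smaller change and a wider error. Counting of intronic reads by the later version may contribute, because genes called higher in PDB had longer introns than genes called lower by 1.71 on the log10 scale (medians 478.6 and 9.5 kb, 2 genes each), while between GDB and NDB the difference was -1.48. The version effect itself had 316 genes higher in 7.0.0 with median introns of 186.2 kb and 31 lower with 2.6 kb. Version and diet are confounded at days 0, 2 and 7. In the 7.0.0 libraries alone, with day 30 as the one NDB library, Cfd (-7.97), Cadm2 (2.03), 6030407O03Rik (4.02) and Chrdl1 (-1.43) kept their direction. The version as the whole cause is left open on 1 NDB library.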

How the results depend on the processing

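The fits to 1 Cell Ranger version alone and those that keep doublets and the clusters with fibroblast and macrophage markers (mixed clusters below) were chosen after seeing the data, and the other alternatives were planned. Counts below are genes called at an adjusted p under 0.05. Against the values reported, single named genes kept their direction and side of the threshold in 1383 values, weakened in 200, strengthened in 17 and reversed in 24 over the alternatives that keep all libraries, and in 1214, 581, 7 and 21 over those that leave out 1 library. Of 132 called named genes, 34 stayed called without each library. Calls were lost in 27 of the 132 with the version term, in 55 with no blocking term, in 17 with doublets kept, in 42 with doublets and mixed clusters kept, in 22 at resolution 2.0, in 8 with the stricter cell filter, in 1 each with RLE factors or no filter and in 0 with DESeq2. Where an alternative tests fewer libraries or more genes, this is the known difference, and for the rest the cause was not tested. GDB day 0 held the fewest macrophage-like (47) and fibroblast-like (161) cells of the 12 libraries.

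In fibroblast-like cells GDB vs NDB gave 5 calls, PDB vs NDB 4, PDB vs GDB 2, and days 2, 7 and 30 gave 1327, 1132 and 24. With no low-count filter the counts were 11 (GDB vs NDB), 651 (PDB vs NDB), 84 (PDB vs GDB) and 542 (day 30). The stricter cell filter gave 3 and 0 for GDB and PDB vs NDB. Resolution 2.0 and the version term gave 1 and 0 for PDB vs NDB. With no blocking term the counts were 1, 0, 1 and, at day 30, 5. Keeping doublets and mixed clusters gave 10 for PDB vs NDB and 4 for day 30. DESeq2 gave 51, 972 and 251 for the arms and 2895, 2222 and 877 for the days. The 6.0.0 libraries alone, with 1 residual degree of freedom, gave 1266 for GDB vs NDB, 2101 for day 2 and 2720 for day 7. The 7.0.0 libraries alone gave 1415, 1061 and 64 for the arms and 2668, 2544 and 1300 for the days. Without 1 library the counts ran from 1 (GDB day 0) to 5 (PDB day 30) for GDB vs NDB. For PDB vs NDB they were 0 (PDB day 0) to 867 (PDB day 30), and for PDB vs GDB 1 (GDB day 7) to 202 (PDB day 30). At day 2 they were 216 (PDB day 0) to 3747 (NDB day 0), at day 7 239 (PDB day 0) to 2302 (NDB day 0), and at day 30 0 (GDB day 30) to 371 (NDB day 30). The causes were not tested.

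In macrophage-like cells the counts were 0 (GDB vs NDB), 1 (PDB vs NDB) and 0 at each day in edgeR. With no filter they were 237, 1141, 477, 301 and 842. The stricter filter, resolution 2.0, the version term and no blocking term each gave 0 for PDB vs NDB, and doublets kept gave 4. Resolution 2.0 gave 1 for GDB vs NDB, 17 at day 2 and 9 at day 7, and the version term 93 at day 2. DESeq2 gave 99, 701, 299, 153 and 716. The 6.0.0 libraries alone gave 157 for GDB vs NDB, 207 at day 2 and 31 at day 7. Without 1 library the counts ran from 0 to 1306 (without PDB day 30) for PDB vs NDB, 0 to 100 (PDB day 30) at day 2, 0 to 3 (NDB day 2) at day 7 and 0 to 865 (PDB day 30) at day 30. In keratinocyte-like cells, where edgeR called 0, GDB vs NDB gave 2 with no filter, 1 at resolution 2.0, 2 with the version term, 1 with no blocking term, 1 with RLE, 65 with DESeq2, 923 with the 7.0.0 libraries alone and 0 to 1 without 1 library (1 without GDB day 2, GDB day 30 or NDB day 30). PDB vs NDB gave 3 with the version term, 671 with DESeq2, 995 with the 7.0.0 libraries alone and 0 to 404 (without NDB day 30).

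Of 15 gene lists in fibroblast-like cells, camera called 6, 6, 6, 6, 12 and 4 for the arms and days in the order above. With an estimated correlation it called 0 in each of the 6 comparisons, with the version term 7, 9, 5, 6, 8 and 5, and with doublets not removed 2 at day 30. Over the 3 classes 74 lists were called, 73 of them not with an estimated correlation and 24 not with the version term. With that term 6 of the 24 turned in direction, all given with the PDB comparisons above. Another 3 turned and were called upward, also given above. Without 1 library 2 called lists turned, proliferation at day 30 in fibroblast-like cells (without NDB day 0) and macrophage carry-over between GDB and NDB in keratinocyte-like cells (without GDB day 0). No class share passed its adjusted threshold with the stricter filter, doublets kept or resolution 2.0, where the lowest adjusted p was 0.1202.

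The difference in shares of fibroblast-like cells between NDB and the other arms became -0.119 points (exact p 0.2222) for Cd14 and C1qa after subtracting the keratinocyte-like share, and 0.051 became 0.358 (0.2222) at resolution 2.0 and 0.753 (0.1728) with mixed clusters kept. For Cd14 it was -2.352 (0.3951) with no thinning and -0.035 (0.9383) after subtraction. For C1qa the 1.044 points (exact p 0.0494) became 1.707 (0.0741) at 2000 UMIs, 2.133 (0.0494) at resolution 2.0, 1.487 (0.1975) with no thinning, 0.929 (0.0864) with the stricter filter, 1.121 (0.0617) with doublets kept, 4.332 (0.1358) with mixed clusters kept too, 0.004 (1.0) after subtraction, and 1.329 (0.0741), 0.659 (0.1852) and 0.716 (0.2222) without day 0, 2 or 7, against 1.47 (0.037) without day 30. The mean distance between days moved from 1.243 to 2.835 in NDB, 1.54 to 3.434 in GDB and 1.271 to 2.569 in PDB over the 1000 most variable genes, which were chosen for their spread, and the arms then ranked otherwise.

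Reversals of single genes were limited to Cd14 and the C1q genes, none of them called in these comparisons. In fibroblast-like cells, GDB vs NDB, the 7.0.0 libraries alone gave Cd14 0.17, C1qa 2.74, C1qb 2.35 and C1qc 2.66. Doublets not removed gave C1qb 0.06 and C1qc 0.08, the version term C1qb 0.04, and mixed clusters kept C1qb 0.12 and C1qc 0.22. For PDB vs NDB the 7.0.0 libraries alone gave Cd14 0.01, C1qa 1.46, C1qb 1.59 and C1qc 0.83. For day 30 vs day 0, Cd14 was 0.01 with RLE, 0.27 with doublets not removed, 0.16 with the version term, 0.05 in the 7.0.0 libraries and 0.02 with DESeq2. C1qa was -0.07 with the stricter filter, -0.44 with no blocking term and -0.31 with mixed clusters kept, C1qb -0.07 with the stricter filter and -0.77 with mixed clusters, and C1qc -0.89 with mixed clusters. Without 1 library, Cd14 for GDB vs NDB ran from -0.61 to 0.17, C1qb from -0.75 to 0.21 and C1qc from -0.75 to 0.48, each highest without NDB day 7, and Cd14 for PDB vs GDB from -0.64 (without GDB day 7) to 0.01 (without GDB day 2). At day 30 Cd14 ran from -0.30 to 0.27, C1qa from -1.06 to 1.51, C1qb from -0.72 to 1.01 and C1qc from -0.79 to 1.40. The cause was not tested.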

Other observations

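The Lepr levels and the split counts within days were looked at after the results were seen, and the other split counts were planned. Lepr also differed between the unreplicated days. In NDB fibroblast-like cells it was 70.1 CPM in unwounded skin, 30.2 at day 2, 16.5 at day 7 and 61.9 at day 30. In PDB it was 135, 10.7, 6.34 and 31.7, and in GDB 32.8, 2.34, 1.54 and 4.41. The GDB fall and NDB day 30 cross Cell Ranger versions, and the clusters of the class changed.

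Other splits of the same libraries were counted for each gene comparison between groups of at least 3 libraries. For GDB against NDB in fibroblast-like cells 1 of 35 splits, the real one, gave 5 genes, and the highest of the others gave 1. Most of those splits mix days, which differ by many genes, so they cannot exclude chance. The 8 that keep 1 library of each day in a group are too few for a share under 0.05. They had 5 genes in the real one and 0 in the highest other. Chance is therefore not excluded. For PDB against NDB chance cannot be excluded, as 2 of 35 splits gave as many as the real 4 and the highest other gave 97. The split with 97, which swaps the day 30 libraries, parts the Cell Ranger versions as the real one does, and points to a structure of the samples. With the version term the real split gave 0 genes in edgeR, with 1002 at an unadjusted p under 0.05 and 972 by DESeq2 without the term. For PDB against GDB chance cannot be excluded either, as 2 of 35 splits gave as many as the real 2 and the highest other gave 1747, which points to a structure of the samples. The 8 splits within days are again too few, with 2 genes in the real one and 0 in the highest other. In macrophage-like cells 35 of 35 splits gave as many as the real 0 between GDB and NDB (highest other 6), and 5 of 35 as many as the real 1 between PDB and NDB (highest other 1046, from the same swap of the day 30 libraries), so chance is not excluded. In keratinocyte-like cells 35 of 35 splits gave as many as the real 0 in both comparisons, with a highest other of 1 for GDB and 12 for PDB. For the days in fibroblast-like cells 10 splits are too few for a share under 0.05. The real counts were 1327, 1132 and 24 at days 2, 7 and 30, reached by 1, 1 and 2 of the splits, and the highest others 0, 0 and 499, the last from a split across arms, which points to a structure of the samples.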
